A study of Micropterus salmoides with 72 samples.

How the data were processed

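Liver and testis RNA of male largemouth bass was measured on 72 single-colour (Cy3) Agilent arrays of a largemouth bass design with 15208 probes for expressed sequences, 536 control spots per array and 15155 different probe sequences. The labels put each array in a lake and a tissue and give it a replicate number. Each of Steiger, Calhoun and Twin had 8 liver and 8 testis arrays, and each of Prior and Medicine had 6 of each. The series' design text calls the arrays of a lake biological replicates and names Prior as the reference for Medicine and Steiger as the reference for Calhoun and Twin.

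The deposited scanner files hold intensity values per spot on a linear scale, made with Agilent Feature Extraction 10.1.1.1 per the file headers, with spatial and multiplicative detrending switched on and no scaling between arrays. The background taken off was the smooth surface fitted across the array, not the local background of each spot. Mean spot brightness and median local background are deposited as intensity values as well, and were used for an alternative. Other deposited columns are flags of 0 or 1 that the scanner software set, per the file headers: well above background, non-uniform spot, outlier among replicate spots, saturated. The authors' deposited value table holds log2 values. Set against the scanner files, each of its columns was log2 of the processed signal of the same array minus a constant that gave a column median of 0, and its 1017 empty cells were the 1017 spots with the non-uniform flag. Its scale and centring were thus known and no direction was open, since it holds no ratios. It was used as an alternative. What the authors did after that table is not given in the sources used here.

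For each array the log2 processed signal was taken relative to the array's 75th percentile, so that a level of 0 is the 75th percentile of that array. Control spots and the non-uniform spots were left out. There were 0 outliers among replicate spots, and the 1 saturated spot was kept. A probe was tested if it was well above background on a share of at least 0.5 of the arrays of 1 or more lakes in the fit. Linear models with moderated variances were fitted with limma 3.58.1 in R 4.3.3 (with data.table, version 1.17.8). The scanner files were read in Python 3.11.15 with pandas 2.3.3 and numpy 2.4.6, and figures were drawn with matplotlib 3.10.9. A probe was called when its Benjamini-Hochberg adjusted p was under 0.05 over all probes tested in that comparison. Every adjusted p of a probe below is from limma. Prior and Medicine were fitted together for each tissue, and Steiger, Calhoun and Twin together for each tissue, so that the 3 lakes shared an estimate of the spread. The lake difference in liver was set against that in testis with an interaction contrast over both tissues, for probes tested in both. Both sets of lakes were hybridised on slides of their own, and the 48 arrays of Steiger, Calhoun and Twin carry an extended-range column that the other 24 lack, so no level was compared between the sets.

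The 12 slides were numbered. All but slide 1, which held a single array, held more than 1 lake, so each result was also fitted with the slide as a block, and the sign of each call was checked within a slide after fitting the other slides alone. Calhoun and Twin share the Steiger arrays. Chance similarity of their differences was therefore simulated with 100 sets of unchanged groups, the overlap of independent lists was computed, and the Steiger arrays were split 4 and 4 in 70 ways. After the results were seen, the arrays of each comparison between lakes were also split at random with the number of arrays of each lake on each slide kept, in all 72 ways for liver Medicine against Prior and 100 for each of the others. For single values per array, exact two-sided permutation tests were used.

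The array files give 0 of the 15208 probes a gene description, and 0 probe identifiers matched the gene table of the assembly ASM1485139v1 used here. Probes are therefore given by their identifier and, for a few, their sequence. The rule fixed before the data were examined named the 10 named genes with the largest rise and the 10 with the largest fall among those called (the 3 with the smallest p in a direction with no call), up to 4 members of each described gene list, and vitellogenin, estrogen receptor 1, CYP1A and PPAR alpha. It could not be applied, and neither could the 30 gene lists fixed with it. In its place, at most 2 probes that were higher and 2 that were lower per comparison are given, those with the largest differences among the calls (or, with no call, the smallest p in each direction), chosen after their values were seen. Where the lists were to be used, probes enriched in liver or in testis were taken, also after the data were examined. For each set of lakes these were the probes at least 8-fold brighter in that tissue than in the other in the other set of lakes, and well above background on a share of at least 0.5 of its arrays, so that no list was chosen on the arrays it was tested on. They made 960 liver-enriched and 688 testis-enriched probes for Steiger, Calhoun and Twin, and 1193 and 721 for Prior and Medicine. Lists were tested with limma's camera at its preset correlation of 0.01, and again with the correlation estimated from the data, with Benjamini-Hochberg adjustment over 16 tests. Under the alternatives camera was run on the moderated t statistics (cameraPR) with the same adjustment, and a list that an alternative does not cover entered with its p from such a run without that alternative. These runs used the preset correlation only. The estimated correlations lay between 0.09 and 0.35, and no list was called with them (camera adjusted p of 0.925 or more), so calls under the alternatives carry the same limit.

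A probe that was well above background on 0 arrays of a group has only a bound there. Its fold is then given as "at least", from the brighter group's mean against the mean, per array of the dimmer group, of the higher of the probe's own level and the lowest level among probes well above background. For arrays, their number limits the precision. Spots of the same sequence on an array differed by a median SD of 0.09 to 0.22 log2 units. Between arrays of a lake the SD was 0.50 to 0.65 for those probes. The SD between arrays holds variation of array and slide as well as variation between fish, and these were not told apart.

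The fits were tested on simulated data with 200 changed probes each, drawn with the mean and residual SD of each real probe. At a 2-fold change, 20% of changed probes were recovered for liver Medicine against Prior (11604 probes), 30% for testis Medicine against Prior (13453 probes), 44% for liver Twin against Steiger (10742 probes) and 50% for testis Twin against Steiger (14407 probes). At a 4-fold change these shares were 78%, 82%, 84% and 96%. False calls made up 6.17%, 8.70%, 4.63% and 3.28% of the calls in these simulations. Each probe was drawn independently, without slide effects or variation shared across probes, so these shares need not hold for the real arrays.

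Alternative settings fixed with that rule were normexp background correction (offset 50) on mean and background intensities, quantile normalization, a 75th percentile over probes detected on all arrays, no filter and a stricter filter on dim probes, outlier spots kept, slide as a block, replicate number as a block, the authors' values, trended and robust moderation, array weights and other groups in the fit. Added after the data were examined were leaving out arrays that stood apart (median correlation with the other arrays over 3 median absolute deviations below the median), leaving out slide 6, removing a trend with probe GC content, and taking the level of the liver-enriched probes as a covariate.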

Results

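The data were expression profiles of livers and testes of male largemouth bass (Micropterus salmoides), a freshwater predatory fish, caught in 5 Minnesota lakes. The series addresses possible effects of perfluorinated chemicals, a class of persistent surfactants, and the lakes stand for sites to be compared with a reference lake. Concentrations of these chemicals were not used here, so each comparison is between lakes. Medicine was compared with Prior (6 arrays per lake and tissue), and Calhoun and Twin with Steiger (8 arrays per lake and tissue). The 75th percentile signal per array ranged from 122 to 684 intensity units in liver and from 660.5 to 3320.4 in testis. Between 48.8% and 78.8% of probes were well above background on the liver arrays, and between 80.7% and 96.8% on the testis arrays. Arrays of a group correlated with r from 0.894 to 0.987 across probes, and 0 pairs were identical.

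Livers from Medicine and Prior differed at 4 of 11604 probes, of which 2 were higher and 2 were lower in Medicine. UF_Msa_AF_107272, with the sequence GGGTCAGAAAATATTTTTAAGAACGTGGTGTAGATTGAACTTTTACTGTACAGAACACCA, was 15.1-fold higher in Medicine, with a log2 difference of 3.92 ± 0.41 (SE, n = 6 and 6, limma adjusted p = 0.0017). It was well above background on 6 of 6 Medicine arrays and on 1 of 6 Prior arrays, so the fold was taken against signals mostly near background. The difference on the 4 slides with both lakes lay between 3.55 and 5.01, and with normexp background correction it was 0.55 (limma adjusted p = 0.576). UF_Msa_AF_104979 was 4.31-fold higher (log2 difference 2.11 ± 0.31, limma adjusted p = 0.0255), well above background on 3 of 6 Prior arrays, with a difference of 0.16 under normexp. UF_Msa_AF_107954 and UF_Msa_AF_100839 were well above background on 0 Medicine arrays and on 6 and 3 of 6 Prior arrays, and were at least 1.81-fold and at least 1.15-fold lower there (limma adjusted p = 0.0208 and 0.0224).

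Of 1187 liver-enriched probes in these livers, 0 were called by limma and 0 with p adjusted over the list alone, and their median log2 difference was -0.21 against -0.04 for the other probes. Camera put the list below other probes (adjusted p = 0.000109), a call lost with an estimated correlation (adjusted p = 0.925). Of 490 testis-enriched probes 0 were called by limma over all probes, and 5 were higher and 25 lower with p adjusted over the list alone, with a median of -0.10 (camera adjusted p = 0.0845). That median ran from -0.42 with normexp (camera adjusted p = 5.36e-08) and -0.24 with the replicate number as a block (0.0206) to -0.013 with no filter (0.436). At the preset correlation camera also called the list without Medicine liver 5 (-0.18, adjusted p = 0.0046). So it did with quantile normalization (0.0146), array weights (0.018), the stricter filter (0.0316) and the authors' values (0.0466), but not in the other alternatives. Within slides the median of the liver-enriched list lay between -0.67 and 0.06, and it was -0.21 in the fit with the slide as a block and 0.018 with normexp, which put the list above other probes (camera adjusted p = 1.53e-07). In liver, 848 probes had an unadjusted p under 0.05, where 580.2 lie by chance. Limma called 3 probes in the fit with the slide as a block, 0 with normexp background correction (445 at an unadjusted p under 0.05), 11 without Medicine liver 5, which stood apart from the other arrays, and 0 to 21 over 14 alternatives. The calls of all 4 probes ended with normexp, where the differences shrank to 0.55, 0.16, -0.76 and -0.78 (for UF_Msa_AF_107272, UF_Msa_AF_104979, UF_Msa_AF_107954 and UF_Msa_AF_100839). They also ended with the replicate number as a block, but there the differences were 4.29, 1.79, -2.15 and -1.94, against 3.92, 2.11, -2.19 and -2.03 in the fit without the block. Their SE of 0.32 to 0.42 compared with 0.29 to 0.41, and the degrees of freedom fell from 14.3 to 6.78. For UF_Msa_AF_107954 and UF_Msa_AF_100839 the differences given here are fitted values, and only the bounds above hold. With quantile normalization the calls of UF_Msa_AF_107954 and UF_Msa_AF_100839 ended (limma adjusted p = 0.0712 for both), as they did with trended and robust moderation (0.132 and 0.158), which also ended that of UF_Msa_AF_104979 (0.0831). In these 2 alternatives the differences lay between 1.95 and 2.19 in size, with larger SE. UF_Msa_AF_107954 was not called with both tissues in the fit (limma adjusted p = 0.129), and UF_Msa_AF_100839 not with the slide as a block (limma adjusted p = 0.0571), with fitted differences unchanged at -2.19 and -2.03. On the slide with 1 array of each lake that held Medicine liver 5, the calls made without that slide kept their sign for 6 of 10 probes.

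In testis, Medicine and Prior differed at 0 of 13453 probes by limma, with 217 probes at an unadjusted p under 0.05, where 672.65 lie by chance. The probe with the smallest p among those lower in Medicine was UF_Msa_AF_100171, with a log2 difference of -1.63 ± 0.35, and among those higher UF_Msa_CF_121100, with 1.09 ± 0.29 (SE, n = 6 and 6, limma adjusted p = 1 for both). The first was well above background on 1 of 6 Medicine arrays (-0.11 with normexp) and the second on 4 of 6 Prior arrays. Liver-enriched probes had a median difference of -0.17 (0 of 1099 called) and testis-enriched probes of -0.065 (0 of 721 called). Both signs turned in alternatives, to 0.064 for the liver-enriched list with the replicate number as a block, and for the testis-enriched list to 0.11 without Medicine testis 8 and 0.038 with array weights. Camera put the liver-enriched list below other probes (adjusted p = 4.74e-08), a call lost with an estimated correlation (adjusted p = 0.925), and its median within slides ran from -0.65 to 0.53, with -0.16 for the slide as a block. The testis-enriched list was not called (camera adjusted p = 0.432, and 0.925 with its estimated correlation of 0.34). At the preset correlation, however, camera put it below other probes with normexp (-0.046, adjusted p = 0.005), the replicate block (-0.14, 6.62e-06) and the liver-probe level as a covariate (-0.22, 2.71e-09), and above them without Medicine testis 8 (1.4e-05). A fit with the slide as a block also gave 0 calls by limma (566 at an unadjusted p under 0.05). In the simulation of this comparison, with independent noise per probe, 82% of 4-fold changes and 30% of 2-fold changes were recovered, so part of the changes of 2-fold would have been missed. The simulation held no variation shared across probes, so the shares on the real arrays are not known.

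**Figure D1:**
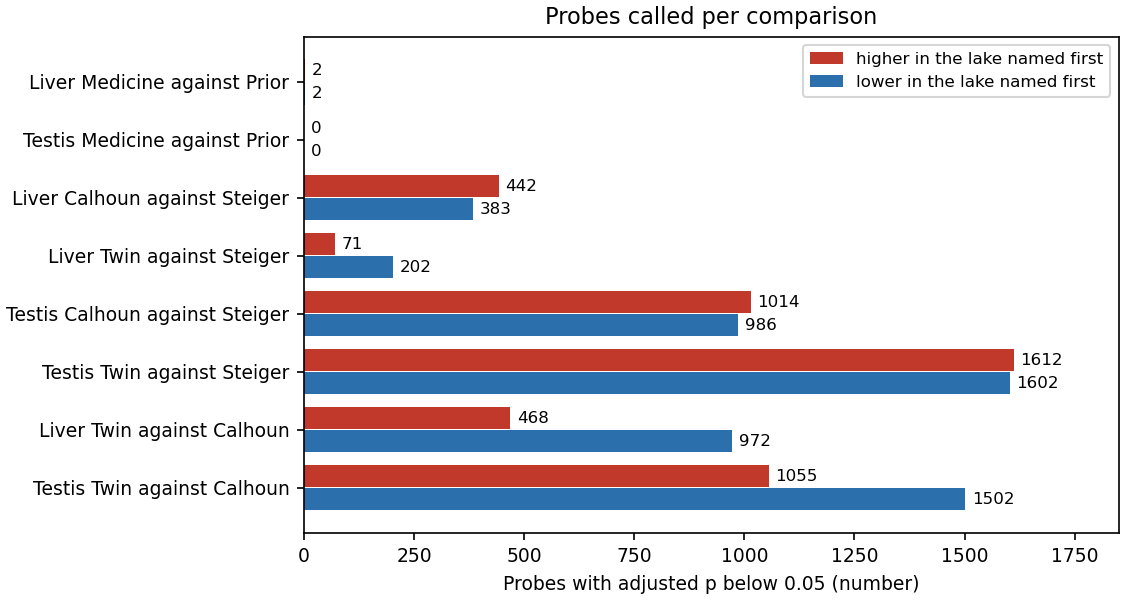
Number of probes called per comparison (adjusted p under 0.05, horizontal axis), higher in red and lower in blue in the lake named first. The pair of Medicine and Prior gave 4 calls in liver and 0 in testis, and the comparisons among Steiger, Calhoun and Twin gave 273 to 3214.

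Livers from Calhoun differed from those of Steiger at 825 of 10742 probes, 442 higher and 383 lower, and 414 of them by at least 2-fold. UF_Msa_AF_101531, with the sequence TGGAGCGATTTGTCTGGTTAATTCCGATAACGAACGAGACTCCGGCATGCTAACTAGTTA, was 22.3-fold lower (log2 difference -4.48 ± 0.69 SE, n = 8 and 7, limma adjusted p = 0.00034), and UF_Msa_AF_104354, with the sequence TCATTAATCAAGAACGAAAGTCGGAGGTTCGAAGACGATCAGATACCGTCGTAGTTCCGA, was 11.1-fold lower (-3.47 ± 0.46, limma adjusted p = 0.000171). The sequences of both raised the question of ribosomal RNA, which was not testable without a reference sequence, so these values are signal differences of RNA of unknown class. The liver-enriched probe UF_Msa_CF_124175 was 10.03-fold higher (3.33 ± 0.68, limma adjusted p = 0.0045) and well above background on 8 of 8 Calhoun and 3 of 8 Steiger arrays. UF_Msa_CF_124502, well above background on 7 of 8 Calhoun arrays, was 5.99-fold higher (2.58 ± 0.72, limma adjusted p = 0.0292). Of 290 testis-enriched probes, 1 was higher and 14 were lower in Calhoun liver (0 and 10 with p adjusted over the list alone), with a median of -0.41.

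Camera put the testis-enriched list below other probes in Calhoun liver (adjusted p = 0.000148), a call lost with an estimated correlation (adjusted p = 0.925). Over all 688 listed probes, the level per array was -4.66 ± 0.54 in Calhoun and -4.33 ± 0.49 in Steiger liver (SD, n = 8 and 8, exact permutation p = 0.218, adjusted p = 0.529 over 16 tests). Only 290 of the 688 passed the filter in liver, so that level rests largely on dim probes. The median difference of the 290 tested probes was -0.32 with the slide as a block and between -0.41 and -0.20 within slides. Of 914 liver-enriched probes, 73 were higher and 41 lower (97 and 67 with p adjusted over the list alone), with a median of 0.062, a mean of -0.007 and no call by camera (adjusted p = 0.151). That median turned to -0.012 with the slide as a block, -0.036 with array weights and -0.023 without slide 6. With normexp it was 0.34 against -0.29 for the other probes and the list was called at the preset correlation (camera adjusted p = 6.19e-14). No run at the estimated correlation was made for this setting. The fit with the slide as a block called 462 probes, 222 higher and 240 lower, of which 432 were among the 825. Without slide 6, which held Steiger and Twin livers only, 294 were called, and with array weights 1605. The 3 arrays of slide 6 had a spike-in fit with an r2 of 0 per the file headers and 131 to 139 non-uniform spots, against at most 43 on any other array. Calls made without a slide kept their sign on that slide for 94.1% to 98.5% of probes. With normexp 406 probes were called, 266 higher and 140 lower, the median of all probes was -0.27, and the calls of UF_Msa_CF_124175 and UF_Msa_CF_124502 ended (0.49 ± 0.37 and 1.39 ± 0.47, adjusted p = 0.337 and 0.0826), while UF_Msa_AF_101531 and UF_Msa_AF_104354 had -3.89 and -2.49. The call of UF_Msa_CF_124502 also ended with the slide as a block (2.21, adjusted p = 0.084) and without slide 6 (2.44, adjusted p = 0.0912).

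Livers from Twin differed from those of Steiger at 273 of 10742 probes, 71 higher and 202 lower, and 160 of them by at least 2-fold. UF_Msa_CF_125732 was 6.25-fold higher in Twin (log2 difference 2.64 ± 0.67 SE, n = 8 and 8, limma adjusted p = 0.0325) and UF_Msa_AF_104452 was 4.33-fold higher (2.11 ± 0.28, limma adjusted p = 0.000189). They were well above background on 5 and 7 of 8 Steiger arrays. UF_Msa_AF_108842, with the sequence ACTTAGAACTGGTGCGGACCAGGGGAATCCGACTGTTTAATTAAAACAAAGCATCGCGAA, was 5.52-fold lower (-2.47 ± 0.51, limma adjusted p = 0.0106), and its sequence raised the same untested question of ribosomal RNA. UF_Msa_AF_108705, with the sequence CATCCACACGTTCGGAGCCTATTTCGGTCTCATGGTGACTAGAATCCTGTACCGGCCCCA, was 4.56-fold lower (-2.19 ± 0.49, limma adjusted p = 0.017) and well above background on 1 of 8 Twin and 7 of 8 Steiger arrays. Of 290 testis-enriched probes 0 were higher and 4 lower by limma (0 and 1 with p adjusted over the list alone), with a median of -0.32. Of 914 liver-enriched probes 10 were higher and 26 lower (16 and 33 over the list alone), with a median of -0.016.

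Camera put the testis-enriched list below other probes in Twin liver (adjusted p = 0.0035), a call lost with an estimated correlation (adjusted p = 0.925). Over all 688 listed probes, mostly dim in liver, the level per array was -4.74 ± 0.67 in Twin and -4.33 ± 0.49 in Steiger (SD, n = 8 and 8, exact permutation p = 0.1795, adjusted p = 0.529 over 16 tests). The liver-enriched list was not called by camera (adjusted p = 0.516), but normexp put it above other probes (0.071, camera adjusted p = 1.09e-07). The testis-enriched median was -0.24 with the slide as a block, where camera did not call the list (adjusted p = 0.0627), and ran from -0.59 to 0.07 within slides. The fit with the slide as a block called 358 probes, 105 higher and 253 lower, and calls made without a slide kept their sign on that slide for 76.4% to 100% of probes. The lowest share, 168 of 220, was on slide 6, whose arrays had the poor spike-in fit and many non-uniform spots given above. With normexp 3 probes were called, all 3 higher, and the calls of all 4 probes named here ended (0.81 for UF_Msa_CF_125732, 0.78 for UF_Msa_AF_104452, -2.27 for UF_Msa_AF_108842 and -0.72 for UF_Msa_AF_108705). Array weights gave 965 calls, no filter 142, and the authors' values 152, with 60 higher and 92 lower. The call of UF_Msa_CF_125732 also ended with no filter (unchanged at 2.64, adjusted p = 0.0548) and without slide 6 (2.52, adjusted p = 0.0894).

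**Figure D2:**
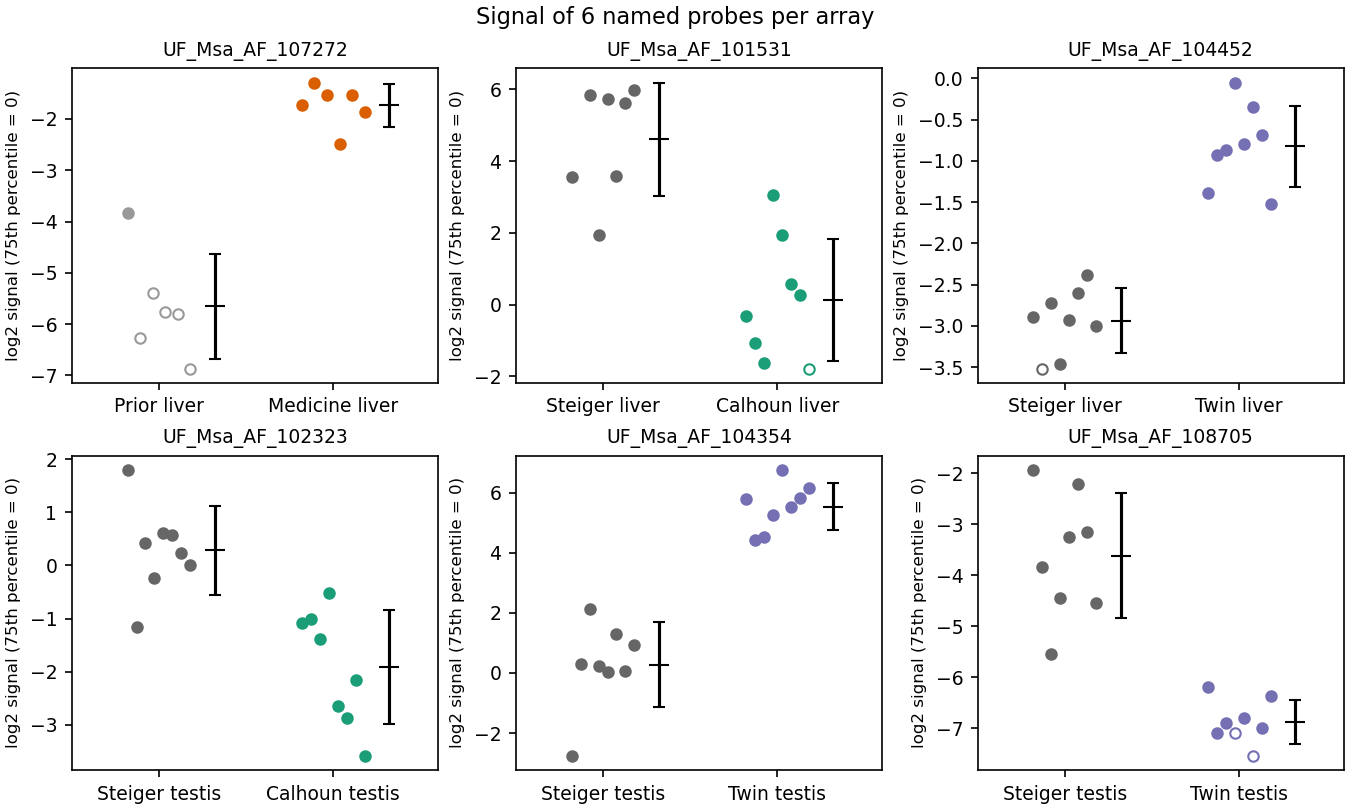
Signal of 6 probes on each array (log2, relative to the 75th percentile of the array), with open circles where the probe was not well above background and bars for the mean and SD of each lake. UF_Msa_AF_104354, whose RNA class is unknown, lay in testis at 5.53 ± 0.79 in Twin and 0.27 ± 1.42 in Steiger, and UF_Msa_AF_107272 in liver at -1.73 ± 0.41 in Medicine and -5.66 ± 1.03 in Prior.

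Testes from Calhoun differed from those of Steiger at 2000 of 14407 probes, 1014 higher and 986 lower, and 553 of them by at least 2-fold. Calhoun testis arrays were also dimmer. Their 75th percentile signal was 1575 ± 567 intensity units, against 2437 ± 555 in Steiger and 2086 ± 435 in Twin (mean ± SD, n = 8 each). On average 89.96% of probes were well above background in Calhoun testis and 92.66% in Steiger testis. Whether this brightness affected the calls or their split into higher and lower was not tested. The largest rises were in liver-enriched probes. UF_Msa_AF_100703 was 10.99-fold higher in Calhoun (log2 difference 3.46 ± 0.92 SE, n = 8 and 8, limma adjusted p = 0.0139), with 2.57 when Calhoun testis 2 was left out, 2.46 with normexp and 1.87 with the level of the liver-enriched probes as a covariate. UF_Msa_CF_124056 was 6.14-fold higher (2.62 ± 0.70, limma adjusted p = 0.0142), and 2.19 ± 0.74 with that covariate, where the call ended with an adjusted p of 0.0516, a smaller difference and a larger error. Over 17 alternatives its difference lay between 2.12 and 2.77. UF_Msa_CF_124968, well above background on 5 of 8 Calhoun arrays, was 4.72-fold lower (-2.24 ± 0.47, limma adjusted p = 0.0023), and UF_Msa_AF_102323 was 4.57-fold lower (-2.19 ± 0.40, limma adjusted p = 0.000732). Of 897 liver-enriched probes tested in testis, 70 were higher and 14 lower (40 and 10 with p adjusted over the list alone), with a median of 0.47 against 0.10 for the other probes.

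Camera put the liver-enriched list above other probes in Calhoun testis (adjusted p = 0.000481), a call lost with an estimated correlation (adjusted p = 0.925). Per array, the level of the liver-enriched probes was -3.53 ± 0.61 in Calhoun and -4.14 ± 0.33 in Steiger (SD, n = 8 and 8, exact permutation p = 0.0084, adjusted p = 0.111 over 16 tests). The list's median was 0.48 with the slide as a block, between 0.21 and 0.69 within slides, and 0.32 without Calhoun testis 2, where camera did not call it (adjusted p = 0.0837), nor with array weights (0.37, adjusted p = 0.0512). Of 688 testis-enriched probes 11 were higher and 46 lower (7 and 33 over the list alone), with a median of -0.0076 and a mean of 0.04 (camera adjusted p = 0.0963), and the sign of the median depended on that array, being 0.18 without it. With normexp it was 0.065 against 0.32 for the other probes (camera adjusted p = 7.02e-06), and with the liver-probe level as a covariate 0.305 against 0.10 (0.0041), on the other side of them. The fit with the slide as a block called 1991 probes, 1878 of them among the 2000, and calls made without a slide kept their sign on that slide for 92.3% to 97.6%. The median of all probes was 0.12 with scaling to the 75th percentile and -0.0045 with quantile normalization, and the calls were then 580 higher and 1352 lower. With array weights 3963 were called. With normexp, 4416 were higher and 1043 lower, the median of all probes was 0.31, and the call of UF_Msa_CF_124968 ended (-0.39, adjusted p = 0.0583). Its difference was -1.55 with array weights.

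Testes from Twin differed from those of Steiger at 3214 of 14407 probes, 1612 higher and 1602 lower, and 968 of them by at least 2-fold. UF_Msa_AF_104354 was 38.2-fold higher in Twin (log2 difference 5.26 ± 0.87 SE, n = 8 and 8, limma adjusted p = 0.000188), with values of 5.08 to 5.38 on the 3 slides. It is one of the probes whose RNA class, messenger or ribosomal, was not settled. The liver-enriched probe UF_Msa_CF_125783, with the sequence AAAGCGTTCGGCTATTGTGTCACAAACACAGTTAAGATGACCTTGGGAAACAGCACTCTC, was 30.5-fold higher (4.93 ± 1.22, limma adjusted p = 0.0054) and well above background on 5 of 8 Steiger arrays. Its difference was 4.22 without Twin testis 1, 2.73 with normexp and 1.80 with the level of the liver-enriched probes as a covariate. UF_Msa_CF_124800 was 9.77-fold lower (-3.29 ± 0.82, limma adjusted p = 0.0059) and UF_Msa_AF_108705, lower in Twin liver as well, was 9.60-fold lower (-3.26 ± 0.49, limma adjusted p = 5.78e-05). Both were well above background on 6 of 8 Twin arrays. With normexp these differences were -1.62 and -1.48, and without Twin testis 7 that of UF_Msa_CF_124800 was -2.70. Of 897 liver-enriched probes 182 were higher and 44 lower (202 and 48 with p adjusted over the list alone), with a median of 0.32, and of 688 testis-enriched probes 74 were higher and 53 lower (63 and 48 over the list alone), with a median of 0.28.

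Camera put the liver-enriched list above other probes in Twin testis (adjusted p = 0.002), a call lost with an estimated correlation (adjusted p = 0.925) and not called without Twin testis 1, where the median was 0.22 (adjusted p = 0.0886). Per array, the level of these probes was -3.33 ± 0.81 in Twin and -4.14 ± 0.33 in Steiger (SD, n = 8 and 8, exact permutation p = 0.0138, adjusted p = 0.111 over 16 tests). The list's median was 0.31 with the slide as a block and between 0.03 and 0.45 within slides. The testis-enriched list was not called (camera adjusted p = 0.0953). Its median ran from 0.19 with array weights (camera adjusted p = 0.275) to 0.39 without Twin testis 1 (0.0031) and 0.70 with the liver-probe level as a covariate (1.14e-10). The fit with the slide as a block called 3185 probes, 3011 of them among the 3214, and calls made without a slide kept their sign on that slide for 97.2% to 98.5%. With quantile normalization the calls were 1208 higher and 1929 lower.

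**Figure D3:**
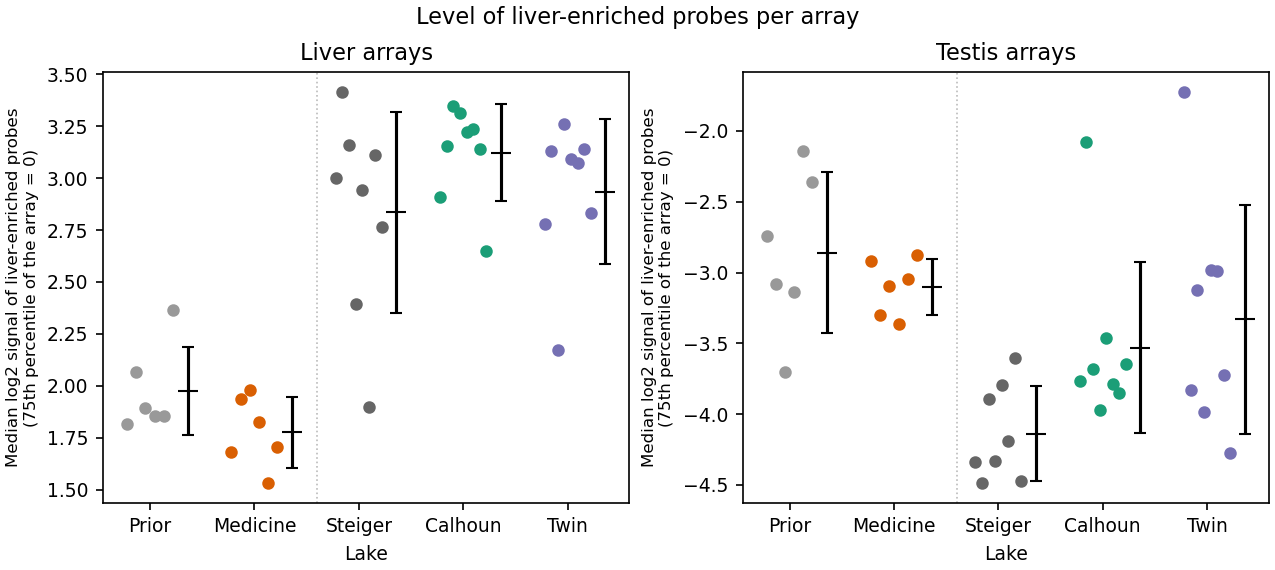
Median log2 signal of the liver-enriched probes on each array (relative to the array's 75th percentile) in liver and testis, with bars for the mean and SD of each lake; the dotted line parts the lake sets, whose lists and slides differ. In testis the mean was -4.14 in Steiger, -3.53 in Calhoun and -3.33 in Twin, and the highest arrays were Twin testis 1 at -1.72 and Calhoun testis 2 at -2.08.

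Calhoun and Twin were also set against each other. In liver 1440 of 10742 probes differed, 468 higher and 972 lower in Twin, and in testis 2557 of 14407, 1055 higher and 1502 lower. UF_Msa_AF_108705 was lower in Twin in both tissues, 9.24-fold in liver (log2 difference -3.21 ± 0.49 SE) and 24.3-fold in testis (-4.60 ± 0.49, n = 8 and 8 in each tissue, limma adjusted p = 0.000129 and 1.04e-05). In liver it was well above background on 1 of 8 Twin arrays, so that fold was taken against signals mostly near background, and with normexp the differences were -0.51 in liver and -2.68 in testis. UF_Msa_AF_103323 was 9.42-fold lower in Twin liver (-3.24 ± 0.51, limma adjusted p = 0.00019, and -1.35 with normexp), well above background on 6 of 8 Twin arrays. In liver UF_Msa_CF_124848 and UF_Msa_AD_200117, well above background on 5 and 6 of 8 Calhoun arrays, were 11.2-fold and 9.76-fold higher in Twin (limma adjusted p = 0.000238 and 0.0017). The log2 difference of UF_Msa_CF_124848 went from 3.48 to 1.77 with normexp, and that of UF_Msa_AD_200117 from 3.29 to 2.55 without Calhoun liver 6. UF_Msa_AF_105410 was 13.8-fold lower in Twin testis (-3.79 ± 0.71, limma adjusted p = 0.0013, and -2.93 with array weights). In testis the liver-enriched probe UF_Msa_AF_100941, well above background on 3 of 8 Calhoun arrays, was 13.5-fold higher in Twin, with a wide error (3.76 ± 1.15, limma adjusted p = 0.0266). Its difference was 3.06 without Twin testis 1 (limma adjusted p = 0.0512), 4.59 without Calhoun testis 2, 4.87 with array weights, 3.01 with the level of the liver-enriched probes as a covariate and 1.77 with normexp. The liver-enriched probe UF_Msa_AD_200102, well above background on 2 of 8 Calhoun arrays, was 11.4-fold higher (3.51 ± 0.995, limma adjusted p = 0.0175). Its difference was 2.83 without Twin testis 1, 4.18 without Calhoun testis 2 and with array weights, 2.85 with that covariate, and 1.16 with normexp, where it was not called (limma adjusted p = 0.1225).

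The fits with the slide as a block called 1490 and 2566 probes, and signs held within slides for 92.5% to 97.4% of calls in liver and 88.2% to 97.5% in testis. With normexp 348 were called in liver, and the call of UF_Msa_AF_108705 in liver ended (adjusted p = 0.422), as did that of UF_Msa_AF_100941 in testis (adjusted p = 0.0861). With the authors' values, which are centred on the median, the testis calls were 1909 higher and 948 lower. In testis, 73 testis-enriched probes were higher and 22 lower in Twin than in Calhoun (median 0.21, camera adjusted p = 0.000423, and 0.925 with an estimated correlation; 0.05 without Calhoun testis 2 (adjusted p = 0.0837), 0.33 without Twin testis 1 (1.58e-06) and 0.028 with array weights (0.0512)), and the liver-enriched list was not called (42 higher, 87 lower, median -0.03, mean 0.16, camera adjusted p = 0.895). In liver neither list was called, with a median of 0.0041 and a mean of -0.0081 for liver-enriched probes (camera adjusted p = 0.475, and -0.068 with normexp, adjusted p = 2.83e-06) and 11 testis-enriched probes higher and 16 lower (camera adjusted p = 0.224). The median of the testis-enriched probes was 0.14, on the other side of 0 from the balance of these calls.

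The probes called for Calhoun and for Twin against Steiger overlapped, and the overlap was set against chance. In testis 864 probes were called for both lakes, 851 of them in the same direction, where independent lists would share 223 in the same direction. In liver 33 were called for both, 30 in the same direction, where independent lists would share 10.12. Because both lakes are compared with the same Steiger arrays, unchanged groups already gave a simulated r of 0.501 in each tissue, against observed values of 0.507 in testis and 0.347 in liver. They gave 0 shared calls, but unchanged groups yield few calls at this threshold, so that 0 is no reference for the observed overlap. The covariance of the differences was 0.177 in testis against 0.051 simulated, and 0.0969 in liver against 0.064. With Steiger split into separate arrays for each lake, in 70 ways, the median r was 0.384 in testis (0.205 to 0.506) and 0.101 in liver (-0.07 to 0.31), and the median number of shared calls was 299.5 and 4. In the same direction the median was 293 in testis and 2.5 in liver. Independent lists with the calls of these splits would share a median of 45.6 in testis and 0.61 in liver. Whether tissues differ in this overlap was not tested.

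**Figure D4:**
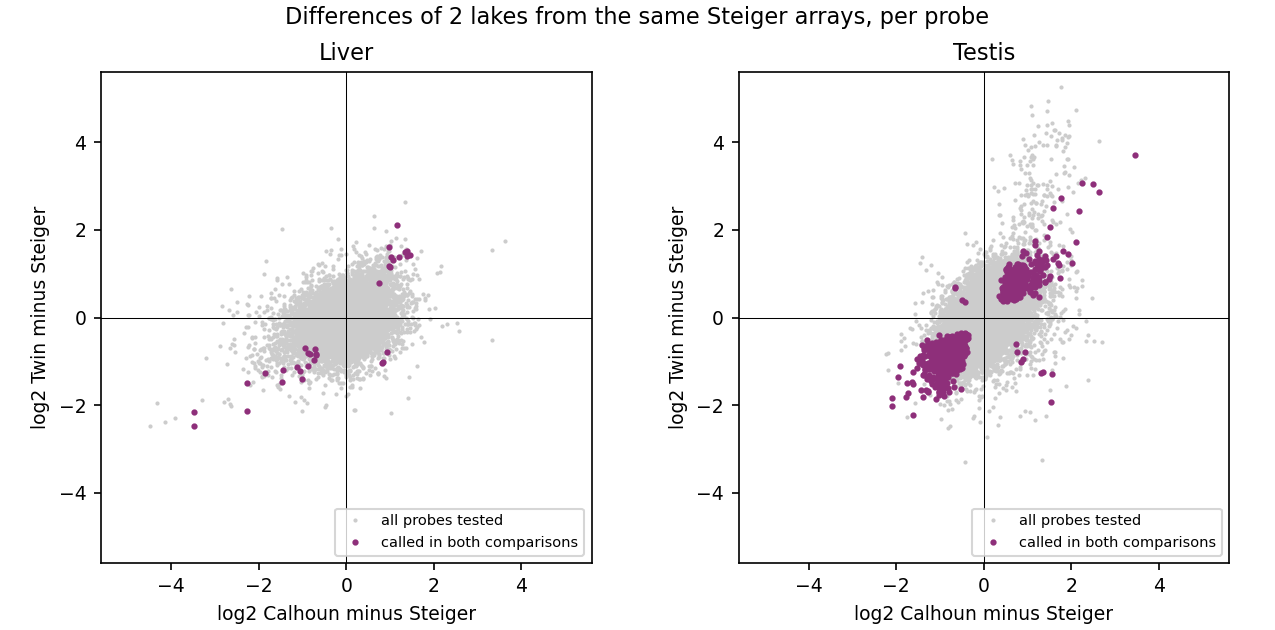
Log2 differences from Steiger per probe, Calhoun on the horizontal and Twin on the vertical axis, in liver and testis, with probes called for both lakes in purple. The purple points number 33 in liver and 864 in testis, of which 30 and 851 lie in the quadrants of the same direction.

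The difference between lakes itself differed between liver and testis at 1528 of 10683 probes for Calhoun and 1237 for Twin, and at 1 of 11399 for Medicine, UF_Msa_AF_107272 (difference of 4.33 ± 0.49, limma adjusted p = 4.19e-05). Liver and testis arrays were treated as separate fish, in these fits and in the splits of their arrays, since the labels do not pair them. UF_Msa_AF_104354 was lower in liver and higher in testis of Twin (log2 differences from Steiger of -2.16 and 5.26, interaction -7.41 ± 1.01 SE, limma adjusted p = 1.5e-05). UF_Msa_AF_108842 was lower in liver and higher in testis as well (-2.47 and 4.01, interaction -6.47 ± 1.05, limma adjusted p = 9.66e-05). UF_Msa_AF_101531 rose in Twin testis (2.80 ± 0.66, limma adjusted p = 0.0039), and its value in Twin liver was -2.48 (limma adjusted p = 0.052, interaction -5.28 ± 0.98, limma adjusted p = 0.000434). For Calhoun the interactions of UF_Msa_AF_104354 and UF_Msa_AF_101531 were -5.22 ± 1.01 and -5.48 ± 0.98 (limma adjusted p = 0.00041 and 0.000165). Whether these 3 probes detect messenger or ribosomal RNA was not settled, so their values need not be those of a gene's transcript. Between Medicine and Prior they differed by -0.10, 0.20 and -0.03 in liver and were not called.

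Of the probes called for Calhoun in both tissues, 41 of 143 went in the same direction and 102 in opposite directions, where independent lists would give 60.8 and 61.0. Among those at least 2-fold in both tissues, 10 of 24 went in the same direction and 14 in opposite directions. For Twin, 45 of 72 went in the same direction and 27 in opposite directions (34.4 and 33.9 for independent lists). Across the 10683 probes the liver and testis differences correlated with r = -0.0873 for Calhoun and 0.0241 for Twin, where probes are not independent replicates. In the fit with the slide as a block, the interaction called 1352 probes for Calhoun, 1177 for Twin and 1 for Medicine. With array weights 2854 and 2635 were called for Calhoun and Twin. With normexp the counts were 2735, 378 and 0 (369 at an unadjusted p under 0.05). The median of all probes in the Calhoun interaction was -0.13 and, with quantile normalization, -0.00043, where 916 calls were higher in liver and 559 lower in place of 744 and 784. For Twin quantile normalization gave 717 higher and 500 lower in place of 550 and 687.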

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

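The tests of liver RNA, of chance between arrays, of the spread within lakes, of the slide in the comparison of Medicine and Prior, of splits within slides and without single arrays were chosen after the results were seen. Of 84 groups of arrays examined for a single array far from the others, 8 held one (9.52%), where chance gives about 1 in 20. UF_Msa_CF_124502 lay at -2.20 on Calhoun liver 1, and the nearest of the other Calhoun livers lay at 0.85. UF_Msa_AF_108842 lay at 3.49 on Steiger liver 8, and the nearest Steiger liver lay at 5.93. UF_Msa_AF_104354 lay at -2.76 on Steiger testis 7, and the nearest Steiger testis lay at 0.046. The level of the liver-enriched probes was 2.17 on Twin liver 3, against 2.78 on the nearest array. Slide 6 held this array as its 1 Twin liver, and Steiger liver 4 and Steiger liver 6 on that slide lay at 2.39 and 1.90. The other Steiger livers lay at 2.76 or more. The 75th percentile signal was 684 on Steiger liver 8, against 287 on the nearest array. The percentage of probes well above background was 96.8 on Steiger testis 6, against 93.2 on the nearest array. On Calhoun testis 2 the level of the liver-enriched probes was -2.08 (nearest -3.46) and that of the testis-enriched probes was -1.58 (nearest -0.56). The lake difference differed between liver and testis, by an interaction contrast, at 1 probe for Medicine, 1528 for Calhoun and 1237 for Twin.

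Of 100 splits of the arrays, the real one included, 1 gave as many calls as the real split for each of liver Calhoun against Steiger (825, highest other 1), liver Twin against Steiger (273, highest other 2), testis Calhoun against Steiger (2000, highest other 377), testis Twin against Steiger (3214, highest other 150), liver Twin against Calhoun (1440, highest other 69) and testis Twin against Calhoun (2557, highest other 573). The same held for the interactions of Calhoun (1528, highest other 472) and Twin (1237, highest other 65). Chance was thus argued against for these 8 counts, at the smallest share that 100 splits can give. The splits for the interactions did not keep the slides, and no splits within slides were run for them. For liver Medicine against Prior 2 of 100 splits gave as many calls (4, highest other 14), but these splits did not keep the slides balanced, and slide explained 76.9% of the first principal component. Of all 72 splits that kept the number of arrays of each lake on each slide, 1, the real one, gave as many (4, highest other 3). Chance within slides was thus argued against by a margin of 1 probe only, in a test chosen after the results were seen. It was not excluded, since the count was 0 by limma with normexp and with the replicate block (445 and 733 at an unadjusted p under 0.05). With normexp the 4 differences shrank to 0.55, 0.16, -0.76 and -0.78, while with the replicate block they were 4.29, 1.79, -2.15 and -1.94, against 3.92, 2.11, -2.19 and -2.03 in the fit without the block, on 6.78 in place of 14.3 degrees of freedom. The negative values are fitted differences of probes for which only a bound was reported. Splits of this kind gave as many calls in 1 of 100 for liver Calhoun (highest other 21), liver Twin (21), testis Calhoun (1) and testis Twin (1462) against Steiger, and for Twin against Calhoun in liver (3) and testis (1), the real one included. The split with 1462 calls left 14 of 16 arrays with their own lake, so it differed from the real one by 1 exchange of arrays, and the structure of samples it points to is largely that of the lakes. The liver Medicine split with 3 calls left 10 of 12. For the Medicine interaction 8 of 100 splits that ignored the slides gave as many calls (1, highest other 101), so chance was not excluded. For testis Medicine against Prior all 100 such splits did (0 by limma, 217 at an unadjusted p under 0.05), as did all 100 within slides (highest other 1). The split ignoring slides with the most calls (1714) placed 10 of 12 arrays on the sides of the first principal component, which held 43.8% of the variance and of which lake explained 0.748% and slide 38.2%. It points to a structure of these samples other than the lake.

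The median of the liver-enriched probes was higher in testes from Calhoun and Twin than from Steiger, with 70 and 182 of 897 probes called higher and 14 and 44 lower, and the list call was lost with an estimated correlation (adjusted p = 0.925), without Calhoun testis 2 (0.0837) and without Twin testis 1 (0.0886). Probe GC content was argued against, since the median difference was 0.47 for Calhoun and 0.32 for Twin once the GC trend was removed. Liver RNA in the testis samples stays a candidate explanation, and the labels name no step that would remove it. Of the 50 liver-enriched probes brightest in liver, 100% and 96% were higher (mean level 9.78 in liver, and -0.10, 1.51 and -1.44 in Calhoun, Twin and Steiger testis). Such a count cannot tell liver RNA from another shift that these probes share. The median excess was 0.202% and 0.848% of their liver level, and it was 0.0566% without Calhoun testis 2 and 0.270% without Twin testis 1 (98% and 90% of probes higher). From the 10th to the 90th percentile of probes it ran from 0.059% to 1.40% in Calhoun and 0.27% to 2.27% in Twin. Whether 1 common share of the liver level underlies these was not tested. Chance between arrays stays open, with exact permutation p = 0.0084 and 0.0138 that became 0.111 after adjustment over 16 tests, and Twin testis 1 and Calhoun testis 2 lay highest, at 6.95 and 5.24 above the Steiger mean for these 50 probes. A change in the testis itself with lake stays open and untested, and 897 of the 960 liver-enriched probes passed the filter in testis.

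Probes called for Calhoun in both tissues went in opposite directions for 102 of 143. Probe GC content and the arrays that stood apart were argued against, since 72.1% went in opposite directions with the GC trend removed and 77.2% without Calhoun liver 1 and Calhoun testis 2. With the slide as a block it was 68% (51 of 75), with normexp 60% (63 of 105), and among calls of at least 2-fold in both tissues 14 of 24. Chance differences between fish stay open, since 47 of 100 splits of the testis arrays correlated with the liver differences as far from 0 as the real one (r of -0.0873, largest other size 0.217). A response to lake that differs between tissues stays open and untested beyond the interaction.

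Medicine and Prior differed at few probes, 4 in liver and 0 in testis by limma (848 and 217 at an unadjusted p under 0.05). A wider spread within lakes was argued against, since the median residual SD was 0.973 and 0.991 times that of the other lakes in liver and testis. Slide effects as the whole cause were argued against, with 3 and 0 calls by limma once the slide was a block (1091 and 566 at an unadjusted p under 0.05), though in testis the unadjusted count rose from 217 with the block and slide explained 93.2% of the second principal component. The smaller number of arrays was argued against in testis, where draws of 6 arrays per lake gave a median of 781 calls for Calhoun (366 to 2600), but stays open in liver, where the lower median was 39 calls, for Twin (0 to 474), and 32 and 17 of 100 draws for Calhoun and Twin gave at most 10. A smaller difference between these lakes stays open and untested, and so does variation between testis arrays that hides one, since the unadjusted count was 1062 with the liver-probe level as a covariate and 748 with array weights, where 672.65 lie by chance.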

How the results depend on the processing

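The settings without the arrays that stood apart, without slide 6, with the GC trend removed and with the liver-probe level as a covariate were chosen after the data were examined, as were both probe lists. Over 460 alternatives for the 30 named differences, 429 kept direction and side of the threshold, 31 kept direction and lost the call, and 0 turned. The 429 include UF_Msa_CF_121100 and UF_Msa_AF_100171 of testis Medicine, which were never called and stayed so in 15 alternatives each. Losses gathered in normexp, which ended the calls of all named probes of liver Medicine and liver Twin and of some in other comparisons. The probes were chosen for large differences, so few turns of direction could occur. Counts ran from 294 to 1605 for liver Calhoun, 3 to 965 for liver Twin, 1795 to 5459 for testis Calhoun and 3053 to 4728 for testis Twin, and were 0 by limma in all 15 alternatives for testis Medicine (217 at an unadjusted p under 0.05 as reported, 566 with the slide block, 748 with array weights and 1062 with the liver-probe level as a covariate, where 672.65 lie by chance). As few as 48.8% of probes were well above background on a liver array and 80.7% on a testis array. Means over the probes of a gene and the alternatives for the planned gene lists were not run, since no probe had a gene name.

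For the values that follow, the cause was not tested, and fewer arrays or more probes tested are named only where a setting changed them. The normexp offset of 50 intensity units, added to every signal, by itself shrinks the log2 differences of dim probes. How much of each change it made was not tested. Normexp gave 0 calls for liver Medicine by limma (445 at an unadjusted p under 0.05), 406 for liver Calhoun, 3 for liver Twin, 5459 for testis Calhoun, 348 for liver Twin against Calhoun, and, for the interactions, 0 for Medicine by limma (369 unadjusted), 2735 for Calhoun and 378 for Twin. Array weights gave 7 for liver Medicine, 1605 for liver Calhoun, 965 for liver Twin, 3963 for testis Calhoun, and 2854 and 2635 for the interactions of Calhoun and Twin. For liver Medicine, quantile normalization gave 2 calls, the authors' values 7, trended and robust moderation 1, both tissues in the fit 21, and leaving out Medicine liver 5, with fewer arrays, 11. The authors' values gave 152 for liver Twin, and no filter, with more probes tested, 142. Leaving out slide 6, with fewer arrays, gave 294 for liver Calhoun. The Medicine interaction without the arrays standing apart was 2.

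Slide and replicate number were also run as blocks. The slide as a block gave 462 for liver Calhoun. The replicate number as a block gave 0 for liver Medicine by limma (733 at an unadjusted p under 0.05), 800 for liver Calhoun and 1888 for testis Calhoun. Across lakes, arrays of 1 number had a mean r of 0.061 over 4 pairs and 0.070 over 24 pairs in liver, and -0.084 over 3 pairs and 0.033 over 24 pairs in testis, against -0.0073, -0.010, 0.016 and -0.0036 for other numbers. In the same order, arrays of other numbers had 0.029, 0.086, 0.081 and 0.024 on the same slide, and -0.017, -0.035, -0.013 and -0.014 on different slides. Number and slide were thus not told apart. Whether numbers pair arrays across lakes was not tested, and the labels name no such pairing.

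These medians of the lists turned in the comparisons of Medicine with Prior and of Calhoun and Twin with Steiger. Turns in the comparison of Twin with Calhoun are not listed here. For liver-enriched probes, normexp gave 0.0178 for liver Medicine and 0.0706 for liver Twin. The replicate block gave 0.0642 for testis Medicine. In liver Calhoun the slide block gave -0.0118, array weights -0.0361 and leaving out slide 6 -0.0225. In liver Twin, outlier spots kept gave 0.0108 and the authors' values 0.0497. For testis-enriched probes in testis Medicine, array weights gave 0.0381 and leaving out Medicine testis 8 gave 0.1081. In testis Calhoun the median was 0.0648 with normexp, 0.001 with the 75th percentile over detected probes, 0.1464 with array weights, 0.0185 with the GC trend removed, 0.305 with the liver-probe level as a covariate, 0.1772 without both arrays standing apart, and -0.0076 to 0.1772 when 1 of them was left out.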

Other observations

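The tests of pairs of probe orientations and of arrays with the same number were chosen after the data were examined. UF_Msa_AF_107272, the probe with the largest difference between Medicine and Prior livers, also varied among the other lakes. In liver it was lower in Calhoun than in Steiger (log2 difference -2.15 ± 0.57 SE, n = 8 and 8, limma adjusted p = 0.0223), and its value for Twin was -0.45 (limma adjusted p = 0.769). In testis it was lower in Calhoun (-0.66, limma adjusted p = 0.0124) and higher in Twin (0.70, limma adjusted p = 0.005).

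The array held 197 sequences with a probe for each orientation by name, of which 2 pairs were exact reverse complements. In liver both probes of 110 pairs were detected, the forward probe alone of 32, the reverse probe alone of 29 and neither of 26. In testis these counts were 133, 29, 27 and 8. Across pairs, which are not independent replicates, the differences from Steiger of both probes correlated with r = -0.0057 for Calhoun and 0.282 for Twin in liver, and with 0.220 and 0.356 in testis. For Twin both probes of 11 pairs were called in testis, 8 of them in the same direction, and of 0 pairs in liver by limma. For Calhoun both probes of 6 pairs were called in liver and of 5 pairs in testis, with 1 pair in the same direction in each tissue.

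The labels number liver and testis arrays alike but do not say that a number stands for 1 fish. If it did, both tissues of a number may deviate together from their lake's mean. The mean r across probes for arrays of the same lake and number was 0.119 over 8 pairs in Prior and Medicine, against -0.015 for other numbers of the same lake (permutation p = 0.02, one-sided, 6 of 8 pairs above 0), and 0.0534 over 24 pairs in the other lakes, against -0.0078 (permutation p = 0.00019, one-sided, 14 of 24 pairs above 0), with 100000 resamples each. The own number was the best match for 3 of 8 and 9 of 24 arrays. Numbers that mark fish could give such values, as a hypothesis. The resampling did not keep the slides, and other causes shared by number, such as the slide or the order of work, were not tested.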
